A study of Arabidopsis thaliana with 9 samples.

How the data were processed

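Small RNA was sequenced from leaves of 3-week-old Arabidopsis thaliana plants of 3 genotypes, with 3 libraries each. Per the labels' protocols, RNA of 19 to 24 nt was cut from a gel, ligated to adapters at both ends, reverse transcribed and amplified for Illumina sequencing. Per the submitters' processing notes, the reads were handled with Bowtie 1.1.2 and the TAIR10 genome. The counting tool, the miRNA annotation and the treatment of reads that map to several places are not given in the sources used here. The authors deposited raw counts per mature miRNA entry, as whole numbers, with no normalization, and each of the 9 libraries had 427 entries. The deposited counts cover miRNA entries and no other small RNA, so their sum mixes sequencing depth with the share of miRNA in a library and is not the depth of the library. Absolute depth, and with it any change that affects most miRNAs alike, cannot be read from these totals.

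All 427 entry names were matched to mature miRNAs of the RefSeq annotation of the TAIR10.1 assembly, from which coordinates, sequences and host genes were taken. In 43 entries all 9 libraries had 0 counts, and 384 entries had counts. Identical count rows were kept once, which left 368 distinct profiles. Among the 384 entries, 119 shared their mature sequence with another entry, and near-identical counts of such copies (the miR166 entries, for example) mean that a read of a shared sequence was apparently counted for each copy. Members of a family with shared sequences are therefore not independent measurements, and their split between genes is uncertain.

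Genotypes were taken from the sample titles. The main test was edgeR 4.0.16 (quasi-likelihood, robust, limma 3.58.1, R 4.3.3) on the deposited counts with TMM scaling. Low entries were removed by filterByExpr, which left 270 entries. All 9 libraries entered a single fit with genotype as the only term, and p-values were adjusted by Benjamini and Hochberg with a limit of 0.05. CPM values are TMM-scaled, log2 fold changes come with their standard error (SE), and group values are mean ± SD over 3 libraries. TMM assumes that most entries do not change, so its fold changes are relative to the average miRNA of these libraries. As an alternative fixed in advance, libraries were scaled by the summed counts of 2 lists with 109 entries, the late annotation entries (family numbers of 5000 and above) and early entries later questioned as miRNAs. This is called reference scaling here, and it assumes that those entries were at a constant level. Where a group had 0 counts in all libraries, a fold is a lower bound computed against 3 counts over the group.

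Fixed lists, 15 in number, were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. The lists were conserved families, late entries, questioned early entries, DCL4-dependent families, triggers of secondary siRNAs, families tied to DCL1 and AGO transcripts, copper, phosphate, sulphate, auxin, phase change, leaf shape, NLR defence, the miR159 and miR319 families (precursors cut from the loop towards the base), and passenger arms of conserved families. Passenger share was the count of passenger arms, taken by name from the list, as a percent of both arms of conserved families. It and the summed counts were compared by an exact two-sided permutation test, in which 3 against 3 libraries cannot give a p below 0.1. Named entries followed a rule: among entries past the limit with a mean of at least 10 CPM and no overlap between the libraries of the 2 groups, the 10 largest changes in each direction, plus the 10 most abundant entries and the 3 most abundant tested members of each list. Members of that set that were near-copies of another were left unnamed, except miR157b-3p. The groups, the tests, the lists, this rule and all alternatives except 4 were chosen before the data were examined. The 4 added later were a single entry per mature sequence, reference scaling by the median ratio, reference scaling without miR8175, and passenger share without miR398.

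Scripts were tested on simulated counts of the 270 entries with 10 simulations each. For chr2 against WT, 73.7% of simulated 2-fold changes and 90.3% of 4-fold changes were called, with 3.6% false calls. For se-2 against WT these values were 54.3%, 85.3% and 5.4%, so that false calls lay slightly above the limit. A simulated 4-fold drop of all entries outside the reference lists in se-2 (log2 of -2) gave a median log2 of -1.98 with reference scaling and of -0.22 with TMM. Alternatives covered scaling (DESeq2 1.42.0 size factors, total counts), the test (DESeq2, limma-voom), filters, the samples in the fit, replicate number as a block, sums per family, a test against a 1.5-fold change, and leaving out each library. Replicate pairs of a genotype differed by more than sampling noise (chi-square per degree of freedom of 2.85 to 95.5), so no library was a copy of another. The labels do not say whether the libraries came from separate plants, so p-values measure only the spread between these libraries, which may be technical. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were also used.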

Results

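Mature miRNAs were counted in leaves of wild type (WT), se-2 and chr2 plants, with 3 libraries per genotype. The se-2 line is a mutant of SERRATE (SE, AT2G27100, chromosome 2, 11572397 to 11576658, plus strand), a zinc finger protein that works with the nuclease DCL1 to cut primary miRNA transcripts. The chr2 line is a mutant of CHR2 (annotated as BRM, AT2G46020, chromosome 2, 18922533 to 18932055, plus strand), the ATPase of a SWI/SNF chromatin remodelling complex. Small RNA data do not measure the transcripts of the mutated genes, so the genotype labels were not checked. All coordinates are those of TAIR10.1. The study's title frames the comparisons as the effect of CHR2 and of its partner SE on miRNA production.

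Counts in miRNA entries were much lower in se-2 than in the other genotypes. They summed to 1416263 ± 157100 (SD, n = 3, range 1280294 to 1588242) in WT, 164981 ± 32657 (SD, n = 3, range 130482 to 195415) in se-2 and 797746 ± 142307 (SD, n = 3, range 637283 to 908635) in chr2. The mean was 8.58-fold lower in se-2 and 1.78-fold lower in chr2 than in WT, and the libraries did not overlap in any of the 3 comparisons (exact two-sided permutation p = 0.1 for each, the smallest that 3 against 3 libraries allow). These sums hold miRNA reads alone and the sequencing depth is unknown, so a ratio of sums mixes depth and miRNA level. The 109 late or questioned entries taken as the reference had 6085 ± 365.8 counts in WT, 4172 ± 179.9 in se-2 and 4606 ± 806.8 in chr2 (SD, n = 3 each). A single entry, miR8175, held 24.5%, 39.8% and 53.6% of these reference counts in the 3 genotypes. Without it, reference counts were 0.546 of WT in se-2, where totals were 0.116 of WT, but 0.466 in chr2, where totals were 0.563, so in chr2 the smaller change of the reference rested on miR8175.

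**Figure D1:**
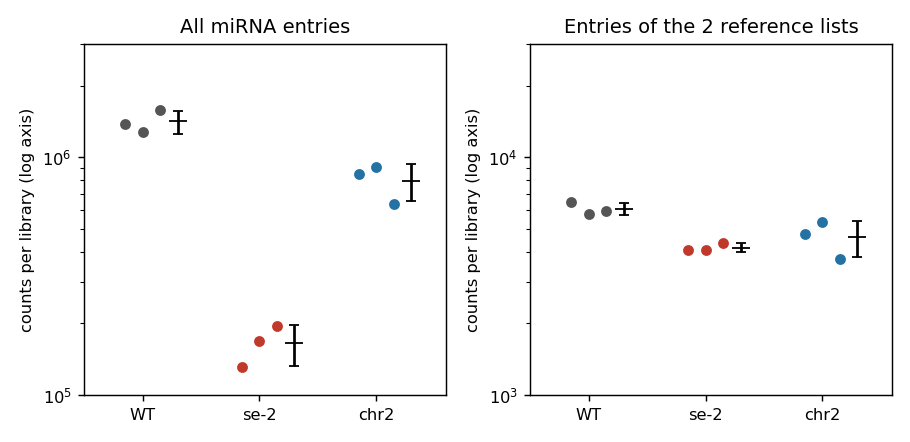
Summed counts per library of all miRNA entries (left) and of the reference entries (right), both on log axes, for WT, se-2 and chr2. Points are libraries and the bar beside them is the mean with its SD (n = 3), and the se-2 libraries lie between 130482 and 195415 on the left, below all other libraries.

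In se-2 against WT, which addresses what loss of SE function does to miRNAs, abundant miRNAs moved both ways within the miRNA pool. The 10 largest entries of each library held 62.0% to 63.1% of the counts in WT and 70.9% to 73.3% in se-2. Among the 10 most abundant entries, 7 were near-copies of miR166, whose shared reads were apparently counted for each copy. The shares are therefore of counts and not of reads. Each of these 7 entries was called higher with TMM (miR166a-3p 93400 ± 4012 against 68240 ± 3948 CPM, SD, n = 3 each). The most abundant entry, miR158a-3p, was at 22420 ± 1608 CPM in se-2 and 148400 ± 8536 CPM in WT (SD, n = 3 each), a 6.62-fold decrease. miR396b-5p, which targets GRF growth regulators, was 6.79-fold lower and miR159b-3p, which targets GAMYB-like factors, 3.24-fold lower. miR840-5p rose from 31.6 ± 2.20 to 1152 ± 83.4 CPM (36.3-fold), and miR857, a miRNA of the low-copper response, rose from 54.6 ± 11.7 to 675 ± 193 CPM (12.4-fold). By edgeR's quasi-likelihood test, 114 of 270 entries were higher and 82 lower in se-2 at an adjusted p below 0.05.

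The direction of many of these calls depended on the scaling. With reference scaling, 15 entries were higher and 193 lower, the median log2 change moved from 0.11 to -2.30 (a shift of -2.39 in scale, a median entry 4.93-fold lower), all 82 decreases stayed, 15 of the 114 increases stayed and 38 became decreases. This downward shift could not turn a decrease into an increase, so only increases smaller than about this shift were open to a change of sign. With DESeq2 size factors, 96 were higher and 118 lower. The changes given below are relative to the TMM average unless reference scaling is named.

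The 10 largest increases that the rule named stayed increases with reference scaling. Their direction was fixed in advance, since the smallest (miR840-3p, log2 3.51) exceeded in size the shift of -2.39. miR2939 (chromosome 5, 19567038 to 19567058, intergenic) had 74.6 ± 28.4 CPM in se-2 and 0 counts in the WT libraries, so it was at least 100.3-fold higher. miR840-5p had a log2 change of 5.18 (SE 0.23, adjusted p 3.2e-17) and of 2.77 with reference scaling. It lies at 771492 to 771513 on the minus strand of chromosome 2, in a UTR exon of AT2G02750 on the same strand, and its partner arm miR840-3p rose by a log2 of 3.51. The other members were miR870-3p (4.31), miR399f (4.11), miR835-3p (3.75), miR845a (3.70), miR857 (3.63), miR4228-5p (3.61) and miR5659 (3.53). Of these, miR399f belongs to a family raised by low phosphate and miR845a matches the primer binding site of retrotransposons. The WT means of miR870-3p, miR399f, miR835-3p, miR845a and miR4228-5p were 2.85, 1.83, 2.98, 3.27 and 4.19 CPM. Their se-2 means were 33.7 to 57.1 CPM, in libraries with 126473 to 190775 tested counts. The sizes of these changes thus rest on few reads, and entries so low in WT could pass the filter through a mutant alone.

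Passenger strands were prominent among the 10 largest decreases. miR396a-3p fell from 1155 ± 127 to 55.6 ± 12.5 CPM (log2 -4.38, SE 0.27, adjusted p 5.4e-14), and miR167a-3p from 1656 ± 142 to 139 ± 43.7 CPM. miR390b-3p (log2 -5.40), miR168b-3p (-3.82), miR169b-3p (-3.60) and miR162b-5p (-3.50) are passenger arms too. In the se-2 libraries miR390b-3p had 7.29, 0 and 0 CPM and miR169b-3p 7.29, 5.81 and 0 CPM, so the sizes of their changes rest on few reads. miR164c-3p, also a passenger arm, had 20.2 ± 3.26 CPM in WT and 0 counts in se-2, at least 3.37-fold lower. Outside the listed passenger arms of conserved families, miR173-5p (chromosome 3, 8236161 to 8236182, intergenic), which triggers trans-acting siRNAs from TAS1 and TAS2 transcripts, fell from 300.8 ± 56.2 to 12.9 ± 8.45 CPM (log2 -4.64, SE 0.46). miR844-3p (-4.41) and miR847 (-3.85) fell as well. By mean share of counts over all 9 libraries, miR173-5p and miR844-3p were the less abundant arms of their hairpins. In the se-2 libraries miR844-3p had 0, 0 and 5.11 CPM and miR847 7.29, 5.81 and 0 CPM, so these values rest on few reads too. Each of these 10 decreases was lower with reference scaling too, which its downward shift fixes in advance.

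Among the fixed lists, 77 of the 127 tested entries of conserved families were called in se-2, 27 higher and 50 lower (camera adjusted p = 2.4e-07, down; adjusted p = 0.059 with an estimated correlation). This list contains the passenger arms given below, and its other 86 entries had 26 higher and 22 lower (a division made after the values were seen). Their median log2 was -0.27, against 1.40 for the entries outside the conserved families. They too thus lay below the entries with which camera compares the list. miR166a-3p, which limits HD-ZIP III factors of leaf polarity, was 1.37-fold higher with TMM but fell by 1.95 on the log2 scale with reference scaling, and DESeq2 size factors ended its call. With reference scaling, 3 conserved entries were higher and 116 lower, with a median 6.75-fold below WT. Passenger arms of conserved families had 1 increase and 28 decreases among 41 (camera adjusted p = 2.4e-07; adjusted p = 0.10 with an estimated correlation), and all 41 were lower with reference scaling. The list included miR157c-3p, 11.3-fold lower, and miR398b-5p, 3.71-fold lower. In WT miR398b-5p was the more abundant arm (14100 against 7750 CPM for miR398b-3p, named after its values were seen). Other listed arms, such as miR160c-3p and miR169f-3p, also exceeded their partners in WT. The tally is therefore of arms listed by name and not of the less abundant arms.

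Families tied to the miRNA machinery fell, with 8 of 11 entries lower and 0 higher (camera adjusted p = 0.0012; adjusted p = 0.24 with an estimated correlation), 4 of the 8 being passenger arms. They comprise miR162, which targets DCL1, miR168 (AGO1), miR403 (AGO2) and miR838, from a DCL1 intron. miR403-3p was 3.05-fold lower, while miR168a-5p had a log2 change of -0.26 and was not called (adjusted p 0.26), although it was called lower with DESeq2 size factors (-0.62) and with reference scaling. Triggers of secondary siRNAs had 8 decreases and 2 increases among 11 entries (camera adjusted p = 0.027; adjusted p = 0.31 with an estimated correlation), including miR161-1 (2.82-fold lower) and miR390a-5p (1.44-fold lower), and the increases became decreases with reference scaling. The auxin list had 12 decreases and 2 increases among 21 (camera adjusted p = 0.0038; adjusted p = 0.12 with an estimated correlation), with miR167a-5p 3.63-fold lower. Phase change entries had 9 decreases and 5 increases among 22 (camera adjusted p = 0.041; adjusted p = 0.39 with an estimated correlation), with miR157c-5p 2.54-fold lower and miR156d-5p at a log2 of -0.33 (adjusted p 0.12). The leaf shape list had 12 decreases and 10 increases among 29 (camera adjusted p = 0.031; adjusted p = 0.44 with an estimated correlation), and all 29 were lower with reference scaling. Outside the passenger arms (a division made after the values were seen), decreases and increases numbered 4 and 0 of 6 in the machinery list, 6 and 2 of 9 among siRNA triggers, 7 and 2 of 12 in the auxin list, 4 and 4 of 15 in phase change and 5 and 10 of 20 in leaf shape.

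The late annotation entries stood on the opposite side, with 42 higher and 7 lower of 52 (camera adjusted p = 2.4e-07, up; adjusted p = 0.12 with an estimated correlation). Among them, miR8175 was 8.96-fold, miR5642a 5.77-fold and miR5026 4.34-fold higher, but the list serves as reference and with reference scaling its median log2 was -0.22 with 3 higher and 17 lower, miR5026 at -0.32. All 6 tested questioned early entries were higher (camera adjusted p = 0.024, and 0.19 with an estimated correlation), miR405b by 5.86-fold, and none was called with reference scaling. Of 104 late and 9 questioned early entries detected, only these 52 and 6 passed the filter. Entries low in WT could pass it through se-2 alone, as miR404 did (3.00 to 6.84 CPM in WT, 36.4 to 52.3 in se-2). The share of increases among tested members is therefore partly set by the filter, although camera passed both lists without it too. The sulphate list, miR395, rose in 5 of 5 entries of 2 distinct sequences (camera adjusted p = 0.013; adjusted p = 0.24 with an estimated correlation), with miR395f 7.20-fold higher, and none of the 5 was called with reference scaling. In the phosphate list 4 of 6 entries rose and 0 fell, which did not pass camera (adjusted p = 0.16). miR399a, 11.2-fold higher, stayed an increase with reference scaling and miR399b (1.58-fold higher) became a decrease of 1.73 on the log2 scale.

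The copper list did not pass (camera adjusted p = 0.11), with 2 increases, miR857 and miR408-3p, against 7 decreases among 11. miR408-3p was 1.51-fold higher with TMM, lost the call with DESeq2 size factors and was lower with reference scaling (log2 -1.80). DCL4-dependent families had 3 increases and 0 decreases among 5 (camera adjusted p = 0.65), with miR839-5p 4.23-fold and miR822-5p 1.61-fold higher. With reference scaling, miR822-5p was lower (-1.72) and miR839-5p was at -0.33 and not called. In the NLR defence list, miR472-5p was 2.36-fold higher (lower with reference scaling) and miR825 2.20-fold lower (2 higher and 1 lower of 3, camera adjusted p = 0.75). The miR159 and miR319 families did not pass as a list (3 higher and 2 lower of 7, camera adjusted p = 0.90), with miR319b 2.35-fold higher (lower with reference scaling) and miR159a at a log2 of -0.12. For each list in se-2, the counts of members adjusted over the list alone equalled those over all entries.

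**Figure D2:**
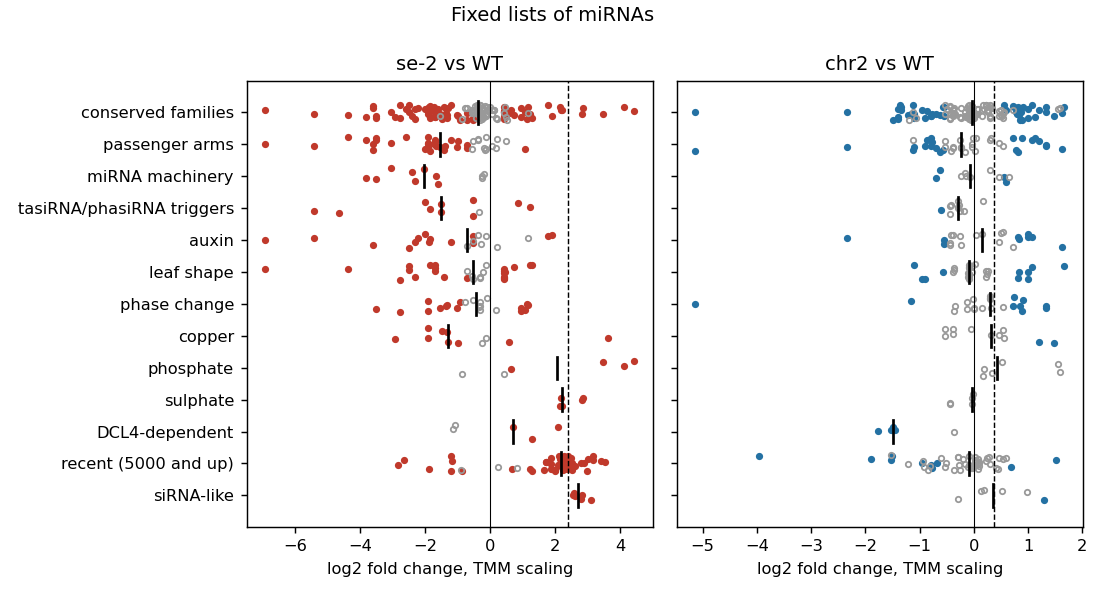
Log2 fold change with TMM scaling of each tested entry (points) in 13 of the fixed lists, se-2 against WT (left) and chr2 against WT (right). Filled points passed the edgeR test at an adjusted p below 0.05, black bars are list medians, the solid line is 0 with TMM and the dashed line is where 0 lies with reference scaling (2.39 and 0.37), so that most se-2 points right of 0 lie left of the dashed line.

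In chr2 against WT, which addresses the effect of CHR2 on miRNA levels, 189 of 270 entries were not called with TMM. That scaling assumes that most entries do not change, and with reference scaling 150 were not called. A small set differed strongly. miR845a was 17.9-fold higher (63.6 ± 13.6 against 3.27 ± 1.42 CPM, SD, n = 3 each), and miR408-3p, a miRNA against copper proteins, 2.77-fold higher (22150 ± 6275 against 7991 ± 2054 CPM). miR156d-3p was 35.2-fold lower (14.97 ± 2.61 against 527 ± 5.04 CPM). miR822-5p, made by DCL4 rather than DCL1, was 3.41-fold lower (552.5 ± 45.2 against 1884 ± 26.6 CPM), and miR393a-3p, the passenger arm of an auxin receptor regulator, 5.09-fold lower. By edgeR's test, 28 of 270 entries were higher and 53 lower, with a median log2 change of -0.15.

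The balance of higher and lower calls in chr2 was not stable. It was 46 higher and 37 lower with DESeq2 size factors, 28 and 35 with total counts, 12 and 108 with reference scaling (a shift of -0.37), and 48 and 27 with reference scaling without miR8175. Decreases numbered 30 without WT replicate 1, 33 without chr2 replicate 1 and 29 without chr2 replicate 3.

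The other large increases in chr2 were miR861-3p (3.42-fold), miR319c, which targets TCP growth factors (3.19-fold), miR8175 (2.86-fold), the passenger arm miR157a-3p (2.51-fold, with its copy miR157b-3p of the same sequence), miR405a (2.45-fold), miR408-5p (2.30-fold) and miR169b-3p (2.19-fold). With reference scaling miR405a (adjusted p 0.099) and miR408-5p (adjusted p 0.052) kept their direction and lost the call. miR845a (chromosome 4, 12217457 to 12217477, intergenic) had a log2 change of 4.16 (SE 0.35, adjusted p 1.1e-10) and of 3.80 with reference scaling. The other large decreases were miR8183 (15.6-fold), miR863-3p (3.71-fold), miR5026 (3.70-fold), miR850 (3.35-fold), miR863-5p (3.31-fold), miR3932b-3p (2.94-fold) and miR822-3p (2.90-fold). In the chr2 libraries miR8183 had 1.37, 0 and 5.38 CPM, so the size of its change rests on few reads. The call of miR3932b-3p was lost without chr2 replicate 1 or chr2 replicate 2 (adjusted p 0.051 and 0.081).

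Abundant miRNAs mostly did not pass the test in chr2. miR158a-3p had a log2 change of -0.24 (adjusted p 0.30), miR166a-3p of -0.10 (adjusted p 0.72) and miR396b-5p of -0.36 (adjusted p 0.12), and each of them was called lower with reference scaling (-0.63, -0.51 and -0.74), but none by its median-ratio form (-0.25, -0.13 and -0.36) or without miR8175 (0.07, 0.19 and -0.04). miR159b-3p fell 1.94-fold and miR157c-5p rose 1.88-fold.

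Of the fixed lists, phase change passed in chr2, with 7 higher and 2 lower of 22 (camera adjusted p = 0.047, up; adjusted p = 0.44 with an estimated correlation), and the call was lost with reference scaling (adjusted p 0.061). Its increases were entries of miR157 and miR156c-3p, and its decreases miR156d-3p and miR156h (miR156c-3p and miR156h lie outside the naming rule and were chosen after their values were seen), while miR156d-5p was at a log2 of -0.12 (adjusted p 0.69). The miR156 and miR157 families hold SPL factors down in juvenile leaves. DCL4-dependent entries fell in 4 of 5 (camera adjusted p = 0.066), namely the 2 arms of miR822 and 2 entries of miR869 (likewise named after their values were seen), with miR839-5p at -0.37 and not called. The 4 are not independent: the miR822 arms come from a single hairpin, and the miR869 entries had near-identical values. Both miR869 entries had 9.60, 4.89 and 3.59 CPM in chr2, so their changes rest on few reads. Conserved families had 22 higher and 25 lower of 127 (camera adjusted p = 0.094; 23 and 29 adjusted over the list alone), and passenger arms 10 and 12 of 41 (camera adjusted p = 0.54; 10 and 15 adjusted over the list alone). In the copper list the arms of miR408 rose and the other 9 of 11 entries were not called (camera adjusted p = 0.15), with miR398b-5p lower only with reference scaling or its median-ratio form. The machinery list had 2 higher and 2 lower of 11 (camera adjusted p = 0.42), with miR168a-5p 1.48-fold higher, a call that reference scaling ended. The auxin list had 6 higher and 3 lower of 21 (camera adjusted p = 0.15; 6 and 5 adjusted over the list alone), with miR167a-5p at a log2 of -0.54 (adjusted p 0.029), a call that was lost with DESeq2 size factors (adjusted p 0.17) and with total counts (adjusted p 0.092). Leaf shape had 6 higher and 4 lower of 29 (camera adjusted p = 0.22), late entries 2 and 8 of 52 (camera adjusted p = 0.96; 1 and 5 adjusted over the list alone), questioned early entries 1 and 0 of 6 (camera adjusted p = 0.15), siRNA triggers 0 and 1 of 11 (camera adjusted p = 0.44; none adjusted over the list alone), and the miR159 and miR319 families 1 and 2 of 7 (camera adjusted p = 0.63). No member was called in the phosphate (camera adjusted p = 0.11), sulphate (0.96) or NLR defence (0.96) list.

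**Figure D3:**
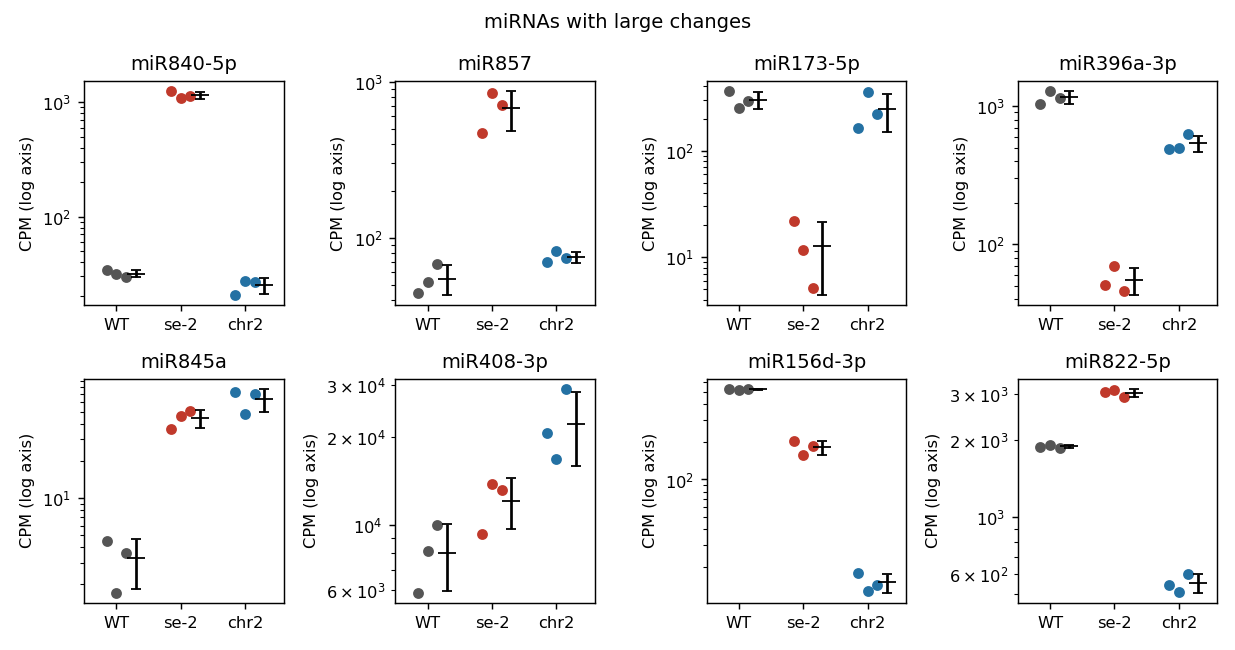
TMM-scaled CPM per library, on log axes, of 8 named miRNAs in WT, se-2 and chr2. Points are libraries and the bar beside them is the mean with its SD (n = 3); miR840-5p averages 31.6 CPM in WT and 1152 CPM in se-2, and miR156d-3p 527 CPM in WT and 14.97 CPM in chr2.

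In chr2 against se-2, the mutants differed in most entries, 89 higher and 128 lower in chr2 of 270 with TMM and 160 higher and 31 lower with reference scaling (a shift of 2.02), while DESeq2 size factors gave 114 and 102. Abundant miRNAs differed in both directions with TMM, miR158a-3p being 5.60-fold and miR396b-5p 5.27-fold higher in chr2, the 7 most abundant miR166 entries called lower (miR166a-3p log2 -0.55, adjusted p 0.0059) and miR159a not called (log2 0.01). Of the 10 largest increases that the rule named, miR390b-3p was 31.6-fold higher in chr2, miR169b-3p 26.6-fold, miR157c-3p 20.9-fold (11900 ± 1208 against 574.6 ± 187 CPM, SD, n = 3 each), miR173-5p 20.5-fold, miR844-3p 17.6-fold, miR168b-3p 17.4-fold, miR847 13.9-fold, miR861-3p 13.4-fold and miR167a-3p 12.4-fold. Of the 10 largest decreases, miR840-5p was 45.7-fold lower, miR5027 30.9-fold, miR850 25.3-fold, miR870-3p 21.5-fold, miR5629 20.7-fold, miR835-3p 18.7-fold, miR8121 17.5-fold, miR870-5p 16.3-fold and miR5026 16.1-fold. These kept their direction with reference scaling, which was fixed in advance, since the smallest (miR5026, log2 -4.01) exceeded in size the shift of 2.02. miR2939 had 0 counts in chr2 and was at least 59.4-fold lower than in se-2, and miR164c-3p was at least 5.91-fold higher. The folds of miR390b-3p, miR169b-3p, miR844-3p and miR847 rest on few se-2 reads, as given above. So does that of miR861-3p, with 0, 0 and 10.2 CPM in the se-2 libraries. That of miR5027 rests on few chr2 reads (1.37, 0.98 and 0 CPM). The folds of miR870-3p (2.74, 3.91 and 0 CPM in chr2) and miR5629 (2.74, 4.89 and 0) do so too. The same holds for miR835-3p (1.37, 2.94 and 1.79 CPM in chr2) and miR8121 (5.49, 2.94 and 0).

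Lists moved in chr2 against se-2 as follows. Conserved families had 60 higher and 35 lower of 127 (camera adjusted p = 4.2e-07; adjusted p = 0.054 with an estimated correlation), of which the 86 outside the passenger arms had 33 higher and 32 lower, passenger arms 27 and 3 of 41 (camera adjusted p = 8.3e-07; adjusted p = 0.089 with an estimated correlation) and the machinery list 11 and 0 of 11 (camera adjusted p = 0.00015; adjusted p = 0.22 with an estimated correlation). Late entries had 6 higher and 43 lower of 52 (camera adjusted p = 8.3e-07, and 0.14 with an estimated correlation), and with reference scaling 8 and 12. Here too, members could pass the filter through se-2 alone. Copper, auxin, phase change and leaf shape passed upwards (camera adjusted p = 0.018, 0.0014, 0.030 and 0.0095) and sulphate downwards (camera adjusted p = 0.018), and with an estimated correlation their adjusted p was 0.41, 0.089, 0.31, 0.31 and 0.29. Outside the passenger arms, higher and lower entries numbered 6 and 0 of 6 in the machinery list, 5 and 1 of 7 in copper, 7 and 2 of 12 in auxin, 6 and 4 of 15 in phase change and 9 and 9 of 20 in leaf shape. The siRNA trigger, questioned early, DCL4-dependent, phosphate, NLR defence and miR159 and miR319 lists did not pass (camera adjusted p from 0.053 to 0.75), the siRNA trigger (0.053) and questioned early (0.063) lists being close to the threshold and passing under several other settings.

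Passenger arms made up 6.01% ± 0.71 of the counts of both arms of the conserved families in WT, 1.75% ± 0.11 in se-2 and 6.18% ± 0.16 in chr2 (SD, n = 3 each). This share compares entries within a library, so scaling does not enter it. It is a percent of counts over 48 passenger and 77 other entries, with shared sequences apparently counted for each copy, and not of reads. It was 4.27 points lower in se-2 than in WT and 4.43 points higher in chr2 than in se-2, with no overlap between libraries (exact two-sided permutation p = 0.1 for both, the smallest possible). chr2 and WT differed by 0.17 points (exact permutation p = 0.7), less than the spread between the WT libraries. The sums cover 23 families, and miR398 alone held 56.8% of the passenger counts in WT, 53.6% in se-2 and 39.6% in chr2. Yet miR398b-5p, listed as a passenger arm, exceeded its partner in WT. So did the listed arms miR160c-3p, miR169a-3p, miR169f-3p, miR169g-3p, miR170-5p, miR171b-5p, miR171c-5p and miR393b-3p. The share thus counts arms listed by name, also without miR398, and not the less abundant arms. Without miR398, a setting chosen after the values were seen, the share was 2.71% ± 0.25 in WT, 0.82% ± 0.07 in se-2 and 3.89% ± 0.43 in chr2 (SD, n = 3 each), with no overlap between libraries in any comparison (exact permutation p = 0.1 each). As a median over 18 families it was 4.79% to 5.27% in chr2 and 5.26% to 5.80% in WT. The fall in se-2 was kept in each form, while the sign of the difference between chr2 and WT depended on how the families were weighed.

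**Figure D4:**
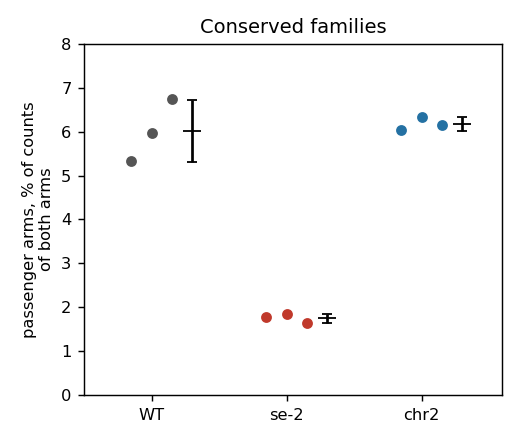
Listed passenger arms as a percent of the counts of both arms of conserved families, per library, for WT, se-2 and chr2. Points are libraries and the bar beside them is the mean with its SD (n = 3); the se-2 mean is 1.75% and the WT mean 6.01%.

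The changes of the 2 mutants against WT correlated weakly. Across 270 entries, which are not independent replicates, the correlation was r = 0.10 (Spearman 0.076). Unchanged groups simulated against the same WT libraries gave a mean of 0.038 (-0.18 to 0.322 over 100 simulations). The covariance was 0.187, against a simulated mean of 0.006 (-0.03 to 0.067), a difference of 0.181. The simulated groups were drawn around the observed WT means, so they leave out the error of those means that both comparisons share. They are therefore no full baseline for the correlation or the covariance, and no conclusion is drawn from them. Calls shared by the mutants numbered 6 higher in both (11.8 for independent lists) and 21 lower in both (16.1), 15 were higher in se-2 and lower in chr2 (22.4) and 12 the reverse (8.5). The 3 WT libraries were not split between the 2 comparisons, so part of any excess may come from the shared controls. miR845a was higher in both mutants, and its changes exceeded the shifts of reference scaling, so it stayed higher. By contrast, miR5026 and miR822-5p were lower in chr2 and, in se-2, higher with TMM and negative with reference scaling.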

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

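Settings added after seeing the data were a single entry per mature sequence, reference scaling by the median ratio, reference scaling without miR8175 and passenger share without miR398. Depth is a limit, since totals hold miRNA reads alone. TMM and reference scaling therefore answer different questions, and no value here decides between their assumptions. The numbers 1 to 3 did not pair the libraries, since none of the 9 correlations of same-numbered libraries exceeded 0.1 (-0.207 to 0.084); with the replicate block the counts of higher and lower entries were 108 and 78 in se-2 against WT, 26 and 47 in chr2 against WT, and 86 and 127 in chr2 against se-2, and libraries did not all correlate best with their own number. Where no cause is named below, the cause was not tested.

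In se-2 against WT, reference scaling gave 15 higher and 193 lower, its median-ratio form 25 and 183, and the form without miR8175 27 and 182. These 3 settings, by construction, shift all log2 changes of a comparison together, and they reversed named increases; those that reference scaling reversed had TMM log2 changes of up to 2.21 (miR395a), below its shift of 2.39. With reference scaling the values were miR166a-3p -1.95, miR5026 -0.32, miR822-5p -1.72, miR839-5p -0.33, miR408-3p -1.80, miR399b -1.73, miR395a -0.19, miR472-5p -1.16 and miR319b -1.17. By median ratio they were miR166a-3p -1.66, miR822-5p -1.41, miR839-5p -0.06, miR408-3p -1.54, miR399b -1.48, miR472-5p -0.88 and miR319b -0.89. Without miR8175 they were miR166a-3p -1.63, miR822-5p -1.39, miR839-5p -0.02, miR408-3p -1.50, miR399b -1.43, miR472-5p -0.84 and miR319b -0.85. No other setting reversed a named entry. Of 101 named values, 78 kept direction and call with reference scaling, 93 with DESeq2 size factors, 95 with the DESeq2 test, 101 with limma-voom and 101 with the replicate block.

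In chr2 against WT, higher entries numbered 46 with DESeq2 size factors, 47 with a minimum of 10 CPM, 12 with reference scaling, 48 without miR8175 and 12 against a 1.5-fold change. Lower entries numbered 35 with total counts, 108 with reference scaling, 31 with the DESeq2 test, 35 with a minimum of 10 CPM, 34 with only the 2 genotypes, 35 with every deposited row, 22 per family and arm, 26 against a 1.5-fold change, 28 per mature sequence and 27 without miR8175; fewer entries were tested per family and per sequence. Leaving out a library gave 29 to 53 lower. In chr2 against se-2 the counts were 160 higher and 31 lower with reference scaling, 175 and 21 without miR8175, and 28 lower by median ratio, whose higher entries lay between those 2 counts and are left unprinted because their number is also a family number in the fixed lists, 57 and 77 per family and arm, and 85 lower per mature sequence.

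For the lists in se-2 against WT, an estimated correlation ended 10 calls (adjusted p 0.0589 conserved, 0.115 late, 0.188 questioned early, 0.314 siRNA triggers, 0.243 machinery, 0.243 sulphate, 0.115 auxin, 0.388 phase change, 0.444 leaf shape, 0.103 passenger arms). Total counts ended leaf shape (0.0770). Sums per family and arm ended questioned early, siRNA triggers and phase change (0.0986 each), and a single entry per sequence ended siRNA triggers (0.0505) and phase change (0.0863). Fry, which does not compare a list with other entries, passed DCL4-dependent (0.00399), phosphate (0.000676) and NLR defence (0.0107), and reference scaling passed phosphate (0.0316). Leaving out a library gave 0.0326 to 0.169 for copper, which passed without WT replicate 1 (0.0326), and 0.0300 to 0.104 for phase change, lost without se-2 replicate 3 (0.104) or chr2 replicate 2 (0.0595).

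In chr2 against WT, phase change was lost with an estimated correlation (0.437), fry (0.835), reference scaling (0.0610), sums per family and arm (0.161) and a single entry per sequence (0.209), and ranged from 0.0177 to 0.0838 over left-out libraries, lost without WT replicate 2 (0.0647) or chr2 replicate 2 (0.0838). The DCL4-dependent list passed with fry (0.00166), DESeq2 size factors (0.0260), total counts (0.0468), no filter (0.0177), 10 CPM (0.0261), the 2 genotypes alone (0.0179), every row (0.0260), per sequence (0.0364), by median ratio (0.0428) and without miR8175 (0.0134), and ranged from 0.0177 to 0.0838 over left-out libraries. Conserved families passed with every row (0.0483) and per sequence (0.0215) and ranged from 0.0226 to 0.252, and copper from 0.0226 to 0.495, over left-out libraries.

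In chr2 against se-2, an estimated correlation ended all 9 list calls (0.0539 to 0.411). The siRNA trigger and questioned early lists passed with fry (0.000666 and 8.12e-05), DESeq2 size factors (0.0266 and 0.0437), no filter (0.0320 and 0.0299), 10 CPM (0.0323 and 0.0383), every row (0.0413 and 0.0429), each form of reference scaling and 8 of 9 left-out libraries, but not without se-2 replicate 3 (0.0625 each), nor with total counts, the 2 genotypes alone, the replicate block, sums per family and arm or a single entry per sequence. Fry also passed the DCL4-dependent, phosphate and NLR defence lists. Copper was lost with reference scaling (0.0887) and its 2 other forms, and copper and phase change with sums per family and arm (0.137 and 0.0693) and per sequence (0.0629 and 0.119); phase change was also lost without se-2 replicate 3.

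Passenger share as a median over families was 2.47 points lower in se-2 than in WT (difference -2.47), 1.99 points higher in chr2 than in se-2, and -0.48 in chr2 against WT. For the share of summed counts, leaving out a library gave -0.18 to 0.53 in chr2 against WT. Without miR398 the differences were -1.89 in se-2 and 1.18 in chr2 against WT, and 3.07 in chr2 against se-2. Ratios of total counts were 0.106 to 0.129 for se-2 and 0.524 to 0.620 for chr2 over left-out libraries, and the correlation of the 2 mutants was 0.068 to 0.115. For the calls of the 3 comparisons, the 10 splits of each set of 6 libraries are too few for a share under 0.05: the real split called 196, 81 and 217 entries, the highest of the others 0 in each, and 1 split of 10 was as large as the real one each time.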

Other observations

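The tests in this part were chosen after the results they bear on were seen, except the search for other miRNA genes near MIR156d.

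miR850, miR863 and miR5026 come from neighbouring genes. Their mature sequences span 2244 bp on the plus strand of chromosome 4, from miR5026 at 7844612 to 7844632 through miR850 at 7845756 to 7845777 to miR863-3p at 7846835 to 7846855, and all are intergenic in the annotation. All 4 tested entries were lower in chr2 than in WT, with log2 changes of -1.89 (miR5026, SE 0.23), -1.74 (miR850, SE 0.32), -1.89 (miR863-3p, SE 0.21) and -1.73 (miR863-5p, SE 0.25), each with 3 libraries below all WT libraries and an edgeR adjusted p of at most 8.1e-05. Reference scaling, which shifted this comparison by -0.37, could only leave them lower. Prompted by this locus, log2 changes of neighbouring miRNA genes from different families (within 10000 bp) were compared with random pairs. Over 13 pairs their median difference was 0.26 in chr2 against WT, where permuted genes gave 0.69 (permutation p = 0.027). Without that locus, 10 pairs remained with 0.37 against 0.69 (permutation p = 0.125), so whether neighbours change together elsewhere stays open. In se-2 against WT, the 13 pairs differed by 1.503 against 2.047 (permutation p = 0.211).

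miR8175, the most abundant of the reference entries, ends in CCA. Its 17 nt before that end match 24 places in the genome, 22 of them at the exact 3' end of annotated tRNA-Asp genes, and the whole 20 nt match 2 places, neither in a tRNA gene. Mature tRNAs carry an added CCA. The entry was higher in chr2 than in WT (log2 1.51, SE 0.22) and in se-2 (3.16, SE 0.24), in 3 of 3 libraries each, and it remained higher with reference scaling (1.13 and 0.71).

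Counts specific to MIR156d were nearly lost in chr2. Raw counts of miR156d-3p (chromosome 5, 3456643 to 3456665, minus strand, in an intron of AT5G10946 on the same strand) were 708, 610 and 738 in WT and 13, 13 and 8 in chr2. The raw log2 ratio of -5.90 lay below the lowest of the 40 other tested passenger arms (-3.12), which argues against fewer reads as the cause. The guide entry miR156d-5p was not called in chr2, but it shares its sequence with other copies, and the counts by which it exceeded miR156a-5p were 4578 ± 164.1 in WT, 449.7 ± 28.4 in se-2 and 64.3 ± 13.7 in chr2 (SD, n = 3 each), at least 55.4 times lower in any chr2 library than in any WT library, so a loss of MIR156d products from both arms may be hidden by shared reads. A sequence variant, insertion or deletion at MIR156d in the chr2 line cannot be told apart from an effect of CHR2 on this gene, because 0 detected entries of other miRNA genes lie within 50 kb and no DNA was analysed here.

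Lower miRNA totals in se-2 have a depth explanation and a biological one. Fewer reads alone would lower all entries alike. The median raw log2 ratio to WT was -0.74 for tested reference entries and -3.38 for tested conserved entries. The difference was at least 2.56 in every se-2 library (up to 2.78), while WT libraries varied from -0.19 to 0.24. Reference entries could pass the filter through se-2 alone, which may widen this difference. Without the filter and without miR8175, summed reference counts in se-2 were 0.546 of WT, where totals were 0.116. Depth alone is therefore argued against as the whole cause. Higher reference entries in se-2 at an unchanged level of other miRNAs cannot be told apart from a loss of miRNAs, because the reference counts were 0.686 of those in WT and the depth is unknown. Reduced processing of primary miRNAs without SE stays open, as untested.

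Passenger arms fell more than guide arms in se-2. The guide was taken here as the arm with the higher mean share of counts over all 9 libraries, se-2 included. In the 29 list hairpins, whose less abundant arm is on the fixed passenger list, the passenger to guide ratio changed by a median log2 of -0.73. In 19 of them the se-2 libraries lay below all WT libraries, and in 5 above (chance gives 10% in total). Listed arms that were the more abundant ones, such as miR160c-3p and miR169f-3p, count as guides here and fall outside the 29. Over all 53 hairpins with both arms, the median was -0.49. The sign of a hairpin's change depends on this rule: miR840-5p counts as the guide, although miR840-3p exceeded it in the WT libraries. Low counts, arm length and reads shared between copies cannot be told apart from a change of the arms. Thinning all libraries to the smallest total left -0.77 and list hairpins with arms of equal length gave -0.94, but over all hairpins neither reached its bound. Sums per family gave -0.91, lower in 16 of 18 families, but the 7 list hairpins whose arms are both unique gave a median of -0.02 with a range from -2.10 to 1.07. These 3 tests were first set, before their values were seen, on all 53 hairpins, where they gave -0.49 after thinning, -0.02 in the 21 hairpins with 2 unique arms and -0.49 in the 37 with arms of equal length. None of these reached the bound of -0.5 set for excluding an explanation, and the value for unique arms met the bound set for sharing as the cause; the list hairpins and the family sums were chosen after that. An effect of losing SE function on the balance of the arms stays open, as untested.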
